A study of Xenopus tropicalis with 18 samples.

How the data were processed

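Thyroid hormone receptor binding was measured by chromatin immunoprecipitation and sequencing in the intestine of stage 54 Xenopus tropicalis tadpoles. The 18 libraries form 6 groups of 3, from 3 genotypes with or without 10 nM T3 for 18 h, and samples were grouped by genotype and treatment per the labels. The labels name the first knockout TRαKO and the series description TRαLKO, and the name of the labels is used.

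Per the labels, the authors aligned reads with Bowtie2 2.3.4.1, called peaks with MACS2 and counted reads with DiffBind, for which no version is given. Per the file headers, MACS 2.2.7.1 was run for each library with no control, a q-value limit of 0.05, a genome size of 2.7e+09 and 1 tag kept per position, although the labels name MACS2 2.1.1.20160309. The last peak ends on the 10 chromosomes sum to 1.45 Gb, below that genome size, and its effect on peak calling was not tested. The deposited count table holds raw read counts for each of 9867 regions in all 18 libraries, made by the authors with DiffBind and not scaled. The deposited peak lists give for each peak the pileup height at the summit in extended tags, not scaled to depth, per the file headers. They also give the MACS p-value and q-value as -log10, per the file headers, and the fold enrichment, a ratio to the local background that MACS took from the same library. The sources do not name the genome build. With the gene positions of UCB_Xtro_10.0, 6.84% of regions lay near a gene end against 3.25% after a shift, and no shift gave the highest share on 10 of 10 chromosomes.

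Library depth was the number of tags after the MACS duplicate filter, per the file headers. It ranged over 12.4 to 17.1 M tags in untreated wild type, 2.29 to 2.53 M tags in wild type with T3, 7.49 to 9.28 M tags in untreated TRαKO, 6.03 to 8.02 M tags in TRαKO with T3, 5.22 to 5.80 M tags in untreated TRβKO and 2.76 to 3.28 M tags in TRβKO with T3. Redundant tags averaged 2.33% in untreated wild type, 21.3% in wild type with T3, 10.0% and 9.67% in TRαKO without and with T3, and 12.0% and 16.0% in TRβKO. Replicates varied 1.86 to 2.28 times as much as counting error alone.

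Counts were fitted in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. One model with the 6 group means was fitted to all 18 libraries by the robust quasi-likelihood method, with the depth above as library size. Of the regions, 9342 passed filterByExpr on the groups. The 12 contrasts were T3 against no T3 in each genotype, the genotypes against each other without and with T3, and the differences between T3 effects. Tests were two-sided quasi-likelihood tests with Benjamini-Hochberg adjustment over all tested regions and a threshold of 0.05. Adjusted p-values given for regions come from this edgeR fit. The p-values measure the spread between these samples. Peak numbers and shares of tags were compared by exact permutation tests in Python 3.11.15 with scipy 1.17.1, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

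The fit was tested on simulated data. It recovered 70%, 92% and 82% of 4-fold rises with T3 in wild type, TRαKO and TRβKO, but 8%, 12% and 8% of 2-fold rises. It recovered 8%, 44% and 16% of 4-fold falls. False calls made up 4.26%, 6.02% and 0% of calls. The simulated counts took their spread from the fit itself, alike in all groups. These shares therefore cannot show errors from a spread that differs between groups. In each genotype 4-fold falls and 2-fold rises were recovered less often than 4-fold rises.

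A region was assigned to the gene whose body it overlaps, or else to the nearest gene within 10 kb. The tests, comparisons, gene lists and named-region rule were chosen before the data were examined. The rule names, for each contrast, up to 12 rises and 12 falls with the largest change among regions past the threshold. These must carry a gene symbol, have a mean level of at least the median of 1.75 CPM, and have 3 libraries of one group all above the 3 of the other, which chance gives in 10% of regions. For differences between T3 effects it names 10 and 10 without the last condition, and between knockouts 5 and 5. It also names thrb, klf9, thibz, mmp11, dio3, dot1l, shh and thra in every contrast, and up to 4 members per gene list. Other genes singled out were chosen after their values were seen.

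The 14 lists covered direct T3 response genes, hormone transport and metabolism, nuclear receptors, coregulators and histone enzymes, hedgehog and BMP, WNT, Notch, apoptosis, matrix remodelling, cell cycle, stem and progenitor cells, differentiated epithelium, mesenchyme, and other cell types. Of their 391 genes, 96 had a tested region within 10 kb, 142 regions in all. Called shares were compared with other gene-assigned regions by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment. This test took regions as independent, although some share a gene or stand in several lists, so its p-values are likely too small.

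Where 1 to 3 reads were left in a group, the ratio of reads per tag is given with its 95% counting interval. Where none were left, and for differences between T3 effects with so few reads in a group, the reads are given and no fold. Intervals cover counting error only.

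Alternatives tried were TMM scaling, DESeq2 1.42.0, no filter on low counts, the replicate number as a block, only the libraries compared, leaving out each library, stricter peaks and another overlap. Scaling by all tags, thinning all libraries to the shallowest, and leaving out mitochondrial and scaffold regions were added after seeing the data. Thyroid hormone response elements were not analysed here because no genome sequence was at hand.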

Results

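Binding of thyroid hormone receptors (TR), the nuclear receptors through which thyroid hormone acts on genes, was measured by chromatin immunoprecipitation and sequencing in the intestine of Xenopus tropicalis tadpoles at stage 54. The animals were wild type, TRα knockout (TRαKO) or TRβ knockout (TRβKO). They were left untreated or given 10 nM of the hormone T3 for 18 h. Each of the 6 groups held 3 libraries, 18 in all, described as biological replicates. An antibody that recognises TR was used, and no input or mock library was analysed here. The counted regions at thra and thrb, the genes of TRα and TRβ, are not informative of the deletions, so the genotype labels were not checked by the targeted gene.

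Depth differed between the groups. Tags kept after the duplicate filter averaged 14.4 M ± 2.46 (SD, n = 3) in untreated wild type but 2.44 M ± 0.131 in wild type with T3. They averaged 8.18 M ± 0.964 in untreated TRαKO, 7.04 M ± 0.998 in TRαKO with T3, 5.50 M ± 0.289 in untreated TRβKO and 2.97 M ± 0.272 in TRβKO with T3. Signal was compared over 9867 regions of median width 453 bp. Each of those on the chromosomes and the mitochondrion was overlapped by a peak in at least 2 libraries, which was not checked for 43 on scaffolds. A gene lay within 10 kb of 6971 of the 9867, and 5278 overlapped a gene body. Levels are in CPM, read counts scaled to the tags of each library, and are given as mean ± SD of 3 libraries.

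Peak numbers differed between groups. Untreated wild-type libraries held 11612 ± 5288 peaks and those with T3 892 ± 78.2. TRαKO libraries held 1182 ± 480.3 peaks without and 4732 ± 1767 with T3, and TRβKO libraries 1382 ± 758.2 and 779 ± 102.9. Among peaks with -log10 q of at least 5 the means without and with T3 were 1313 and 454 in wild type and 163 and 1781 in TRαKO. In TRβKO they were 265 and 485, a rise instead of a fall, and with T3 TRβKO then lay above wild type. Exact two-sided permutation tests of 3 libraries against 3 cannot go below p = 0.1, and 7 of the 9 comparisons reached that value. Exceptions were TRβKO against wild type with T3 (exact p = 0.2) and TRβKO against TRαKO without T3 (exact p = 0.7). The thibz region on chromosome 3 at 140193300 was 1 of 5 regions with a peak in all 18 libraries. Peaks found in at least 2 libraries of a group numbered 542 in wild type with T3 and 552 in TRβKO with T3, and 386 were shared. TRαKO with T3 had 2033 such peaks, of which 382 were shared with wild type with T3. Without T3 the number was 4925 in wild type, 293 in TRαKO and 329 in TRβKO. These groups also differed in depth (14.4, 8.18 and 5.50 M tags). So did wild type, TRαKO and TRβKO with T3 (2.44, 7.04 and 2.97 M tags). None of these peak numbers can therefore be read as numbers of bound sites. Of the 4925, 36 were shared with wild type with T3, 183 with untreated TRαKO and 134 with untreated TRβKO. Leaving out wild-type replicate 2 lowered 4925 to 1674, replicate 1 to 2744 and replicate 3 to 2715. Leaving out 1 library also lowered the TRαKO number to 158 (replicate 1) or 142 (replicate 2), and the TRβKO number to 194, 104 or 170 (replicates 1 to 3). TRαKO with T3 fell to 797 without replicate 2 and 987 without replicate 3.

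The share of tags in the counted regions rose with T3 in every genotype. It was 1.98 ± 0.0396 reads per 100 tags in untreated wild type and 2.90 ± 0.0620 with T3. TRαKO went from 1.67 ± 0.0122 to 2.34 ± 0.115, and TRβKO from 1.81 ± 0.0663 to 2.43 ± 0.0437. All 9 libraries with T3 lay above the 3 untreated libraries of their genotype. An exact permutation of treatment within genotype over 8000 arrangements gave p = 0.00025, two-sided, the smallest it can give. These shares are of tags after the duplicate filter. Per 100 tags before it, libraries without and with T3 held 1.91 to 1.98 and 2.22 to 2.32 in wild type. They held 1.49 to 1.51 and 2.04 to 2.17 in TRαKO, and 1.58 to 1.61 and 2.02 to 2.08 in TRβKO. The direction held, but the size of the rise in wild type depended on the filter.

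**Figure D1:**
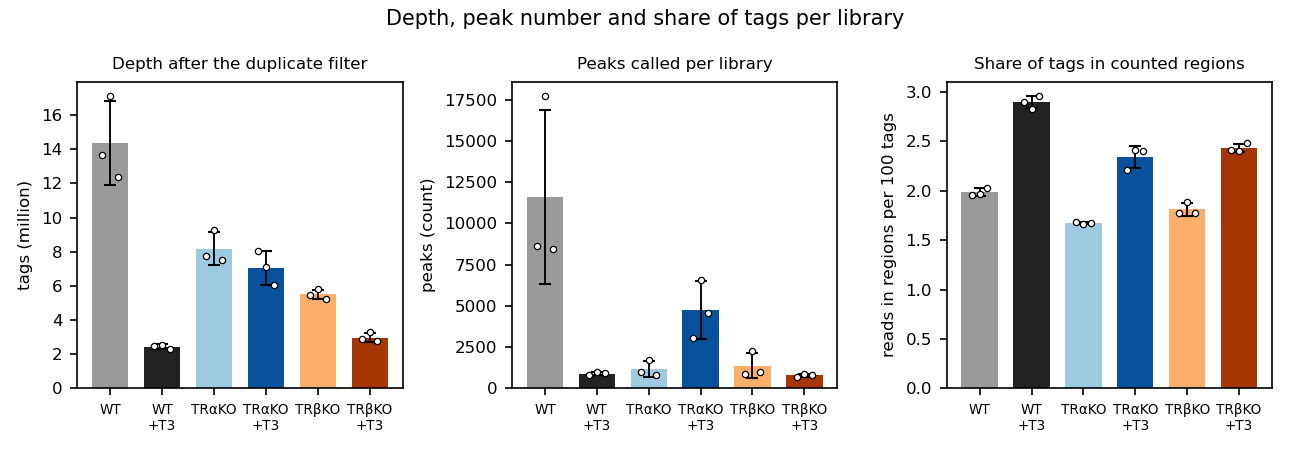
Depth in M tags, number of peaks and reads in counted regions per 100 tags for the 6 groups. Points are libraries, bars means and error bars SD of 3 libraries. Wild type without T3 was the deepest group at 14.4 M tags, and the share of tags in regions was higher with T3 in each genotype.

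The first comparison asked where T3 changed TR signal in the wild-type intestine. At the strongest region of thibz, a leucine-zipper gene switched on by T3 in tadpole tissues, signal rose from 2.71 ± 0.452 to 57.3 ± 3.74 CPM. The thrb gene, which T3 induces through its own receptors, carried 3 counted regions, all of which rose. The strongest, on chromosome 6 at 46932899, went from 2.14 ± 0.711 to 40.2 ± 0.628. The region in dot1l, the gene of a histone H3K79 methyltransferase, went from 1.15 ± 0.363 to 35.8 ± 2.71 (chromosome 1, 102709807). All 4 regions of thra rose, the strongest from 2.13 ± 0.538 to 48.2 ± 1.41 (chromosome 10, 9096138).

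Signal also rose at both regions of klf9, a Krüppel-like factor and direct hormone target. The stronger one, beside the gene on chromosome 1 at 129859818, reached 11.8 ± 2.12 from 1.48 ± 0.313. Among regulators of chromatin and transcription, kdm6b (H3K27 demethylase) rose from 1.64 ± 0.164 to 37.1 ± 5.20, and ezh2 (H3K27 methyltransferase) from 1.26 ± 0.259 to 23.1 ± 4.36. The retinoic acid receptor gene rara rose from 1.55 ± 0.369 to 34.6 ± 3.64, and nr3c2, the mineralocorticoid receptor gene, from 2.96 ± 0.593 to 31.2 ± 1.61. No counted region lay within 10 kb of mmp11, dio3 or shh, which are T3-regulated in tadpole intestine.

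The steepest rises were at genes of several kinds. The region at znrf3, whose product removes WNT receptors from the cell surface, rose by 5.1 ± 0.29 (log2, SE; adjusted p = 8.84e-28) and that at zbtb34 by 5.0 ± 0.26 (adjusted p = 8.58e-30). The activin receptor gene acvr1b rose by 5.04 ± 0.37, the sphingomyelinase gene smpd1 by 5.08 ± 0.40 and gatad2a, a subunit gene of the NuRD complex, by 5.08 ± 0.33. Rises at klhl18 (5.90 ± 0.48), mphosph8 (5.29 ± 0.42), babam2 (5.29 ± 0.49), etfb (5.16 ± 0.49), avpi1 (5.11 ± 0.63) and smarcd2 (5.03 ± 0.51) were of like size. At pgap3, 2 untreated reads against 36 gave a ratio of 106 (95% counting interval 27.4 to 911).

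Falls in wild type were fewer, with a median level of 2.32 CPM untreated and 0.278 with T3. The region at ppm1g, a phosphatase gene, held 167 reads untreated and 2 with T3, 14.1-fold lower per tag (95% counting interval 3.85 to 118, adjusted p = 9.58e-05). At rgs10 the ratio was 7.73 (2.59 to 38.0, adjusted p = 0.00253), with 3 reads left. Falls at tek, pkp2, cd302, nol11, plcd4, golga4, ano7, lhfpl4, bicdl1 and zbtb20 each lost significance without some single library. For plcd4 this happened only without replicate 3 with T3, and for tek only without replicates 1 or 3 with T3. In all, 1057 of 9342 tested regions passed an adjusted p of 0.05 (edgeR quasi-likelihood test, Benjamini-Hochberg, two-sided), 956 higher and 101 lower. TMM scaling lowered the median of all regions from 0.02 to -0.27 (log2), with 902 higher and 241 lower. DESeq2 gave 904 and 240, and scaling by all tags 902 and 273. Of the 101 falls, 66 held 3 reads or fewer in the lower group.

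Fixed gene lists put these changes in context. Regions of 13 direct T3 response genes rose in 20 of 22 cases, including nfic and sox4 beside the genes above, against 12.7% called among other gene-assigned regions (Fisher's exact test, two-sided, adjusted p = 3.75e-15). All 7 regions of the hormone transport and metabolism list rose, but they belong to thra and thrb alone (adjusted p = 2.12e-06). Nuclear receptor genes had 14 of 19 regions higher (adjusted p = 1.00e-08) and coregulator and histone enzyme genes 17 of 26 (adjusted p = 5.01e-09). The lists overlap, so these are not separate results. The 7 regions of thra and thrb are among the 19. The genes kdm6b (5 regions), dot1l, dnmt3a, tet2 and mbd3 stand in both the direct response and the coregulator list. Of 9 regions at genes of the differentiated epithelium, 7 rose (adjusted p = 4.80e-05), among them the brush-border peptidase gene dpp4 (0.920 ± 0.269 to 17.7 ± 2.46) and the intestinal homeobox gene cdx1 (1.34 ± 0.461 to 15 ± 2.95). The apoptosis list had 6 regions higher and 1 lower of 14 (adjusted p = 0.00211), with rises at the death receptor gene fas (0.229 ± 0.0654 to 7.61 ± 2.67) and cdkn1a.

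The remaining lists in wild type had the following counts. Stem and progenitor genes had 3 of 6 regions higher, all of lgr4, a receptor for R-spondins (adjusted p = 0.0642). Hedgehog and BMP genes had 2 higher, ihh and cdon, and 1 lower, gli2, of 8 (adjusted p = 0.129). The fall at gli2 was lost without any of 5 of the 6 libraries. WNT genes had 2 of 21 higher, znrf3 and tcf7l2, cell cycle genes 2 of 6 and matrix genes 1 of 11, adam10. Mesenchyme genes and genes of other cell types each had 1 lower, barx1 of 8 and tek of 5, and Notch genes none of 2. Over all lists, 61 regions were higher and 4 lower of 142, and 61 and 5 when adjusted over the list alone.

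In TRαKO the question was whether T3 still moved TR signal without TRα. It did at the same genes, to lower levels. The strongest thibz region rose from 5.38 ± 1.25 to 20.9 ± 1.44 CPM, and the dot1l region from 3.95 ± 0.855 to 12.6 ± 1.49. The strongest thrb region rose from 4.40 ± 0.572 to 12.8 ± 1.33 and that of thra from 4.48 ± 0.0626 to 19.7 ± 1.51. At the thrb region at 46698245 no change was detected, with 4.85 ± 0.693 untreated and 4.45 ± 0.559 with T3 (adjusted p = 0.833). The stronger klf9 region passed under the main scaling (3.34 ± 0.566 to 7.09 ± 0.350, adjusted p = 0.00382) but not under TMM or DESeq2.

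The largest rises in TRαKO lay at genes of several kinds. At the vitamin transporter gene slc5a6 signal was 3.68 ± 0.388 with T3, on 77 reads against 2, a ratio of 44.7 (95% counting interval 12 to 376). The di- and tripeptide transporter gene slc15a2 rose by 3.32 ± 0.64 (log2, SE), usp21 by 3.12 ± 0.32 and spice1 by 3.23 ± 0.37. Others were edc3 (3.89 ± 0.70), tmtc4 (3.44 ± 0.67), vapb (3.34 ± 0.77), creb3l4 (3.20 ± 0.70), kiaa0930 (3.17 ± 0.55), api5 (3.13 ± 0.76), nat8.9 (3.12 ± 0.70) and midn (3.05 ± 0.56). The named fall, at kiaa0355 (-2.04 ± 0.61, adjusted p = 0.0172), lost significance without untreated replicates 2 or 3 or replicate 3 with T3.

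TRαKO had 810 changed regions, 803 higher and 7 lower. The median of all tested regions was itself 0.46 (log2) above 0, which TMM set to 0.00. TMM called 357 higher and 67 lower, DESeq2 410 and 154, and thinning every library to the shallowest left 356 higher. At the 803 risers the median was 1.73 (log2). Direct T3 response genes had 18 of 22 regions higher (Fisher's exact test, adjusted p = 9.47e-14), nuclear receptor genes 13 of 19 (1.39e-08), coregulator genes 14 of 26 (1.84e-07) and thra and thrb 6 of 7. Differentiated epithelium genes had 4 of 9 and apoptosis genes 5 of 14 (adjusted p = 0.0241 each). Under TMM direct T3 response genes had 11 of 22 regions higher (adjusted p = 4.56e-08) and nuclear receptor genes 9 of 19 (7.91e-07). Epithelium and apoptosis genes then had 2 of 9 (adjusted p = 0.183) and 1 higher and 1 lower of 14 (adjusted p = 0.335), and coregulator genes 5 of 26 (adjusted p = 0.0370). Hedgehog and BMP genes had 2 of 8 (ihh and cdon), WNT genes 3 of 21, cell cycle genes 2 of 6, stem genes 2 of 6, matrix genes 2 of 11 and mesenchyme genes 1 of 8 (zeb2, lost without any of 4 libraries). Notch genes and other cell types had none. Over all lists 54 were higher and 0 lower, and 62 and 1 when adjusted over the list alone.

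In TRβKO, T3 brought TR signal close to wild-type levels at many of these genes. The strongest thibz region rose from 5.33 ± 1.70 to 41.9 ± 5.94, that of thra from 4.56 ± 1.52 to 41.7 ± 9.91 and dot1l from 3.13 ± 0.761 to 25.2 ± 7.76. All 3 thrb regions rose, the strongest from 7.06 ± 1.2 to 32.6 ± 1.17, and klf9 reached 15.9 ± 2.33 from 3.11 ± 1.12. Among the steepest rises were ulk1, an autophagy kinase gene (1.54 ± 0.721 to 28.5 ± 1.09), pik3r1, a PI3-kinase subunit gene (0.910 ± 1.11 to 21.9 ± 4.04), and gys1, a glycogen synthase gene (0.307 ± 0.117 to 7.86 ± 1.90). The region at amn, needed for cobalamin uptake in the gut, rose from 1.02 ± 0.631 to 19.7 ± 2.82. Others were fcho2 (5.70 ± 0.51, log2 and SE), abcc12 (4.73 ± 0.50), ensa (4.65 ± 0.39), avpi1 (4.26 ± 0.70), nsmce2 (4.24 ± 0.61), pmm2 (4.12 ± 0.65), ttc7a (4.08 ± 0.33) and adamtsl5 (4.05 ± 0.38).

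Several falls in TRβKO left few or no reads. The regions in sox6 and galnt18, both on chromosome 4, held 31 reads each untreated and 0 with T3. At gab3 2 reads remained of 57, a ratio of 15.4 (95% counting interval 4.08 to 130), at klc4 10.0 (2.58 to 85.7), at cfap77 9.20 (2.98 to 46.1) and at ebf4 9.02 (2.91 to 45.2). Falls at stab1, cat1, chl1, mgst1, ttll11 and opcml were lost without some single library, such as untreated replicate 3 for stab1 or replicate 1 with T3 for chl1. The hyaluronan receptor gene cd44 fell by 2.15 ± 0.70 (adjusted p = 0.0274), which was lost without any of 3 libraries.

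TRβKO had 1099 changed regions, 887 higher and 212 lower, with a median of -0.16 (log2) over all regions and -0.30 under TMM. TMM gave 863 higher and 323 lower, DESeq2 878 and 284, and a fit of only the libraries compared 849 and 107. Of the falls, 102 were at 3 reads or fewer. Direct T3 response genes had 20 of 22 regions higher (Fisher's exact test, adjusted p = 6.35e-15), nuclear receptor genes 14 of 19 (1.43e-08), coregulator genes 17 of 26 (7.63e-09) and thra and thrb 7 of 7. Differentiated epithelium genes had 6 of 9 (9.03e-04), including the glucose transporter gene slc2a2 and hnf4a, and stem genes 3 higher, of lgr4, and 1 lower, cd44, of 6 (adjusted p = 0.00876). Apoptosis genes had 4 of 14 higher (adjusted p = 0.210), hedgehog and BMP genes 2 of 8, WNT genes 2 of 21, cell cycle genes 2 of 6 and matrix genes 1 of 11. Notch, mesenchyme and other cell type lists had none. Over all lists, 58 were higher and 1 lower, and 61 and 5 when adjusted over the list alone.

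Risers were largely shared between genotypes. Of the 956 in wild type, 839 also rose in TRβKO, where 90.8 would be shared if calls were independent, and 653 rose in TRαKO (82.2 if independent). All 3 genotypes shared 619 of the 1145 regions that rose in any, among them the strongest regions of thibz, thrb, thra and dot1l. The number of TRαKO risers depended on the scaling and depth, and so did its overlaps. Wild type and TRαKO shared 344 risers under TMM, 405 with DESeq2 and 324 after thinning, and all 3 genotypes 330, 398 and 310. Called falls were not shared beyond independence, with 4 between wild type and TRβKO (2.29 if independent) and 0 of the 7 TRαKO falls in either. Simulated 4-fold falls were recovered in only 8% of cases in wild type, 44% in TRαKO and 16% in TRβKO. Falls shared between genotypes could therefore be missed.

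Levels at the risers of one genotype were compared in the genotypes that did not choose them. At the 887 regions that rose in TRβKO, which include the thrb, thra and dot1l regions, wild type went from 1.29 ± 0.0373 to 11.9 ± 0.217 CPM. TRαKO went from 1.80 ± 0.0310 to 4.94 ± 0.0908. At the 956 that rose in wild type, TRαKO went from 1.99 ± 0.0208 to 4.99 ± 0.0817 and TRβKO from 2.15 ± 0.0634 to 11.1 ± 0.210.

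**Figure D2:**
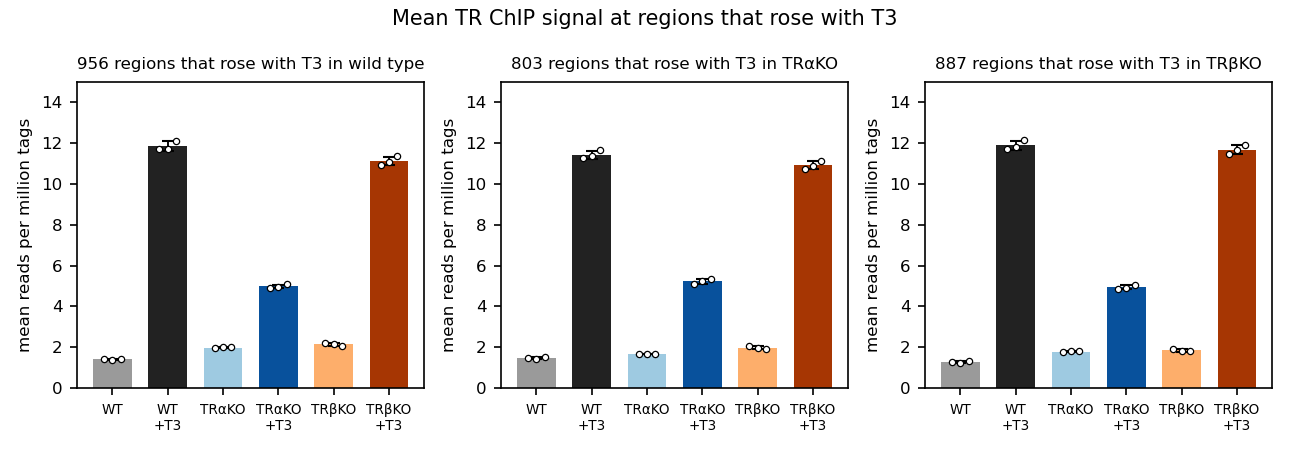
Mean level in CPM over the regions that rose with T3 in wild type, TRαKO or TRβKO, for the 6 groups. Points are libraries, bars means and error bars SD of 3 libraries. In each set the TRαKO libraries with T3 lie between the untreated libraries and those of wild type and TRβKO with T3. At the 887 TRβKO sites TRαKO reached 4.94 and wild type 11.9.

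The next comparison set TRαKO against wild type without hormone. Untreated wild-type libraries stood apart in redundant tags (2.33% against 10% in TRαKO) and depth (14.4 against 8.18 M tags), so library set and genotype cannot be told apart. Of 22 regions at direct T3 response genes, 7 were higher in TRαKO than in wild type and 15 did not pass (Fisher's exact test, two-sided, adjusted p = 1.75e-05). The dot1l region held 3.95 ± 0.855 against 1.15 ± 0.363 CPM (log2 1.75 ± 0.28, adjusted p = 6.84e-06), and kdm6b 4.51 ± 0.607 against 1.64 ± 0.164. The thibz region held 5.38 ± 1.25 against 2.71 ± 0.452, and the thra region at 9098324 2.82 ± 1.03 against 0.850 ± 0.137. At thrb the region at 46932899 held 4.40 ± 0.572 against 2.14 ± 0.711, a call lost without wild-type replicate 3, and that at 46698245 4.85 ± 0.693 against 2.1 ± 0.583, lost without wild-type replicate 2. The region of znrf3 showed 3.68 ± 1.42 against 0.725 ± 0.155. Signal was also higher at mphosph8 (2.63 ± 0.46, log2 and SE), ccnj (2.43 ± 0.45), acvr1b (2.36 ± 0.41), phlpp2 (2.22 ± 0.39), rnpc3 (2.16 ± 0.41), bend7 (2.05 ± 0.38), insr, the insulin receptor gene (1.99 ± 0.41), and bin1 (1.98 ± 0.41).

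Other regions were lower in TRαKO than in wild type without T3. At fam83h signal was 0.565 ± 0.0711 against 4.80 ± 0.231 (log2 -3.04 ± 0.50, adjusted p = 1.64e-05), at znf347 1.77 ± 1.37 against 5.94 ± 0.695 and at samd12 2.91 ± 0.350 against 9.30 ± 0.629. The call at ephx2 (-2.15 ± 0.52) was lost without TRαKO replicate 2 or wild-type replicate 1. Those at slc5a6, sox15, cacng1, mrpl2, wnt9a, mroh1 and rab11fip4 were each lost without any of 4 or more of the 6 libraries.

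TRαKO and untreated wild type differed at 257 regions, 154 higher and 103 lower in the knockout. The median of all regions was -0.28 (log2), 0.06 under TMM and -0.40 with all tags. TMM gave 353 higher and 43 lower, DESeq2 385 and 54, and all tags 128 and 195. A fit of only the libraries compared called 948 regions, 243 higher and 705 lower, with the same median of -0.28. Leaving out TRαKO replicate 2 or 3 gave 155 or 165 regions, and leaving out wild-type replicate 1, 2 or 3 gave 151, 143 or 169. With every library thinned to the depth of the shallowest, 35 regions passed, and none of the calls named above at dot1l, thra, thibz or kdm6b. The median difference at the 887 TRβKO risers was 0.55 (log2) before and 0.56 after thinning. Lists had 14 higher and 1 lower of 142 regions, with 19 and 4 adjusted over the list alone. The lower one was barx1 on chromosome 4 at 151770932, a call lost without any of the 6 libraries.

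TRβKO and wild type without hormone were compared in the same way, with the same 3 wild-type libraries and the same doubt (redundant tags 12% in TRβKO, 2.33% in wild type). Of 22 regions at direct T3 response genes, 7 were higher in TRβKO than in wild type and 15 did not pass (Fisher's exact test, two-sided, adjusted p = 3.19e-04). The thrb region at 46932899 held 7.06 ± 1.2 in TRβKO against 2.14 ± 0.711 in wild type (log2 1.70 ± 0.23, adjusted p = 4.19e-08), and that at 46698245 6.07 ± 0.238 against 2.1 ± 0.583. The dot1l region held 3.13 ± 0.761 against 1.15 ± 0.363 (log2 1.43 ± 0.31, adjusted p = 0.00170). Calls at thibz (5.33 ± 1.70 against 2.71 ± 0.452) and thra at 9096138 (4.56 ± 1.52 against 2.13 ± 0.538) were lost without TRβKO replicate 3. Those at kdm6b and znrf3 were lost without TRβKO replicate 1. Signal was higher by 2.26 ± 0.33 (log2, SE) at epb41l4b, by 3.15 ± 0.56 at gabbr2, by 2.38 ± 0.44 at acvr1b, by 1.97 ± 0.32 at gsdme, which encodes a gasdermin, and by 1.97 ± 0.43 at foxo3. It was also higher at slc13a2 (2.40 ± 0.53), nipal4 (2.09 ± 0.47) and rgs10 (2.09 ± 0.41, at 6400005).

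The lower side again included fam83h, at 0.502 ± 0.481 against 4.80 ± 0.231 (log2 -3.25 ± 0.56, adjusted p = 4.06e-05). The axonemal dynein gene dnah2 held 0.655 ± 0.517 against 3.71 ± 1.16. Calls at the potassium channel genes kcnd1 and kcnh6 were lost without TRβKO replicate 2. Those at fcho2, vav2, pomp, scrt2, acap1, eml2, ftsj1 and kif3b were lost without some single library. TRβKO and untreated wild type differed at 369 regions, 193 higher and 176 lower, with a median of -0.18 over all regions, 0.02 under TMM and -0.33 with all tags. TMM gave 354 higher and 108 lower, DESeq2 379 and 182, and all tags 126 and 289. A fit of only the libraries compared called 971 regions, 345 higher and 626 lower. Leaving out TRβKO replicate 1 or 2 gave 226 or 183 regions, and wild-type replicate 1, 2 or 3 gave 174, 171 or 202. With every library thinned to the depth of the shallowest, 46 regions passed. Lists had 14 higher and 2 lower of 142 (16 and 5 adjusted over the list alone), and the lower ones included gps2, a call lost without any of 5 libraries.

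With T3, the comparison of TRαKO and wild type asked how much lower the hormone-dependent signal was in TRαKO. Their libraries also differed in depth (7.04 and 2.44 M tags) and redundant tags (9.67% and 21.3%), so library set and genotype cannot be told apart. At kdm6b signal was 10.5 ± 0.564 in TRαKO and 37.1 ± 5.20 in wild type (log2 -1.82 ± 0.20, adjusted p = 2.67e-11), and at the strongest thrb region 12.8 ± 1.33 and 40.2 ± 0.628 (-1.66 ± 0.18, adjusted p = 4.08e-11). The thibz region fell short by -1.45 ± 0.16 (log2, SE), dot1l by -1.51 ± 0.20, the strongest thra region by -1.29 ± 0.17 and rara by -1.80 ± 0.21. The nr1d1 region, at the REV-ERBα gene next to thra, held 4.27 ± 0.890 against 17.3 ± 1.81. The clock repressor gene ciart held 6.14 ± 0.878 against 29.7 ± 1.75, the aldolase gene aldoa 3.84 ± 1.2 against 20.6 ± 3.90, and the integrin gene itga7 2.76 ± 1.47 against 14.0 ± 2.79. At klf9 the difference was not detectable (7.09 ± 0.350 against 11.8 ± 2.12, adjusted p = 0.0986).

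Further shortfalls lay at gmppa (-2.75 ± 0.49, log2 and SE), znf687 (-2.57 ± 0.56), gadl1 (-2.52 ± 0.57), tmem168 (-2.50 ± 0.53), sh3d19 (-2.47 ± 0.50), smarcd2 (-2.44 ± 0.45), the retinoic acid hydroxylase gene cyp26b1 (-2.40 ± 0.48) and wwtr1, the gene of the coactivator TAZ (-2.28 ± 0.39). Signal was higher in TRαKO at few genes. At tcf4 67 reads against 2 gave a ratio of 11.6 (95% counting interval 3.08 to 97.6), at tek 61 against 2 a ratio of 10.5 (2.80 to 89.0), and tom1l1 held 5.67 ± 1.42 against 1.07 ± 1.49. Calls at rb1, ppm1g, bicdl1, pip5k1b, zswim8, tff3.5, kcnq5, cd302 and phf19 were lost without some single library, such as wild-type replicate 3 for pip5k1b.

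In all, 783 regions differed between TRαKO and wild type with T3, 101 higher and 682 lower, and the median of all regions was 0.04 (log2), 0.20 under TMM and 0.25 with all tags. Scaling by all tags gave 172 higher and 477 lower, and TMM 144 and 508. Of the 887 TRβKO risers, chosen without these libraries, 550 were lower in TRαKO and 1 higher. At an unadjusted p under 0.05 the whole comparison had 1734 regions, and DESeq2 called 87 higher and 689 lower. Among direct T3 response genes 14 of 22 regions were lower. Lists had 44 lower and 3 higher of 142, 50 and 5 adjusted over the list alone. The 3 higher were rb1, tek and birc5, and the last was lost without any of 4 libraries.

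Most T3-dependent signal was in place in TRβKO, whose libraries with T3 also differed from wild type in redundant tags (16% against 21.3%). With T3, the strongest thra region held 41.7 ± 9.91 in TRβKO and 48.2 ± 1.41 in wild type (adjusted p = 0.559), the strongest thrb region 32.6 ± 1.17 and 40.2 ± 0.628 (adjusted p = 0.370) and klf9 15.9 ± 2.33 and 11.8 ± 2.12 (adjusted p = 0.420). The thibz region (41.9 ± 5.94 against 57.3 ± 3.74, adjusted p = 0.0986) and dot1l (25.2 ± 7.76 against 35.8 ± 2.71, adjusted p = 0.144) did not pass either. At kdm6b signal was lower, 20.5 ± 3.35 against 37.1 ± 5.20 (log2 -0.86 ± 0.20, adjusted p = 0.00473), a call lost without wild-type replicate 2 and under TMM and DESeq2. Signal was higher in TRβKO at epb41l3 (23.8 ± 2.39 against 8.27 ± 2.47), dpp6 (11.9 ± 1.86 against 1.45 ± 1.87) and lpin1, a phosphatidate phosphatase gene (11.7 ± 1.80 against 2.84 ± 0.972). At pip5k1b it was 5.26 ± 0.589 against 0.531 ± 0.460.

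Several regions lower in TRβKO than in wild type with T3 again held few or no reads. The galnt18 region held 0 reads against 28, and sox6 0 against 15, the latter call lost without wild-type replicate 3. At adap2 2 reads against 30 gave a ratio of 18.3 (95% counting interval 4.65 to 158), at arfgef3 16.5 (4.14 to 143), at klc4 15.9 (3.97 to 138), at phactr3 13.8 (4.35 to 70.4), at dgkz 11.4 (3.52 to 58.6) and at nos3, the endothelial nitric oxide synthase gene, 11 (3.38 to 56.6). Calls at cat1, tufm, prpf4b and gab3 below, and at tcf4, edem1, tom1l1, bloc1s2, pex11a, arntl and arhgef7 above, were lost without some single library.

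TRβKO and wild type with T3 differed at 395 regions, 54 higher and 341 lower, against a median of all regions of -0.30 (log2). TMM moved that median to 0.05 and gave 92 higher and 126 lower, and DESeq2 gave 110 and 132. A fit of only the libraries compared called 116 regions, 21 higher and 95 lower. Of the 803 TRαKO risers, chosen without these libraries, 47 were lower and 19 higher in TRβKO. Lists had 3 higher and 7 lower of 142 regions, the same numbers when adjusted over the list alone. The higher ones were nfic, tnfrsf10b and rb1, each lost without some single library, TRβKO replicate 2 among them. The lower ones included tbl1x, a corepressor subunit gene (4.07 ± 1.30 against 11.2 ± 0.265, lost without TRβKO replicates 2 or 3), and cd44 (0.563 ± 0.728 against 4.43 ± 1.79).

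The knockouts were also compared with each other. Without T3 they differed at 58 regions, 38 higher and 20 lower in TRβKO, and none of the regions of the 8 genes named in advance or of the lists passed. At an unadjusted p under 0.05 there were 956 regions, and DESeq2 called 32 higher and 57 lower and TMM 27 and 28. After thinning 12 passed. Named calls, at znf347 (6.69 ± 0.443 in TRβKO, 1.77 ± 1.37 in TRαKO), epb41l4b (9.71 ± 0.617, 3.44 ± 1.94), cacng5, syndig1, exoc2, pnpla3 and tmcc1, were each lost without some library. Without TRαKO replicate 1 this held for znf347 and without TRαKO replicate 3 for epb41l4b. Leaving out TRαKO replicate 3 gave 35 regions and TRβKO replicate 1 gave 37.

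With T3 the target genes had more signal in TRβKO than in TRαKO, in libraries that also differed in depth (2.97 and 7.04 M tags) and redundant tags (16% and 9.67%). The strongest thrb region held 32.6 ± 1.17 against 12.8 ± 1.33 (log2 1.35 ± 0.18, adjusted p = 3.07e-08), thra 41.7 ± 9.91 against 19.7 ± 1.51, thibz 41.9 ± 5.94 against 20.9 ± 1.44, dot1l 25.2 ± 7.76 against 12.6 ± 1.49 and klf9 15.9 ± 2.33 against 7.09 ± 0.350. Signal was also higher at gmppa (3.57 ± 0.46, log2 and SE), gadl1 (3.30 ± 0.52), bloc1s2 (3.27 ± 0.53), mbnl2 (2.58 ± 0.47) and the B-cell survival factor gene tnfsf13b (2.56 ± 0.32). It was lower at galnt18, with 0 reads against 54, and at sox6, with 0 against 48. At prpf4b 2 reads against 90 gave a ratio of 19.0 (95% counting interval 5.11 to 159), at adap2 15.4 (4.12 to 130) and at stab1 13.3 (3.53 to 112). In all 970 regions differed, 584 higher and 386 lower, against a median of -0.39 (log2), -0.21 under TMM. TMM gave 675 and 248, DESeq2 717 and 149, all tags 520 and 546, and thinning 426 and 188. Lists had 43 higher and 4 lower of 142, 49 and 5 adjusted over the list alone.

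Whether T3 acted differently between genotypes was tested as a difference of T3 effects. Larger and smaller refer here to the signed log2 effect, so a deeper fall counts as smaller and a lesser fall as larger. The T3 effect was smaller in TRαKO than in wild type at dot1l (-3.26 ± 0.34, log2 and SE, adjusted p = 4.45e-12), thibz (-2.44 ± 0.26, adjusted p = 6.71e-12), the strongest thrb region (-2.67 ± 0.29) and the strongest thra region (-2.38 ± 0.28). It was smaller at znrf3 by -3.80 ± 0.39 (adjusted p = 1.93e-12), at mphosph8 by -4.29 ± 0.57, at ccnj by -4.07 ± 0.57, at rnpc3 by -3.90 ± 0.52, at babam2 by -4.01 ± 0.69 and at klhl18 by -3.85 ± 0.70. Others were smarcd2 (-3.77 ± 0.77), abcc12 (-3.72 ± 0.61) and gtdc1 (-3.68 ± 0.53). The call at pgap3 rests on 2 untreated wild-type reads. The effect was larger at zswim8 (3.58 ± 0.84) and myo1e.1 (3.23 ± 0.85). Calls at tcf4 and nol11 were lost without TRαKO replicate 2 with T3, and those at ano7, tram2, tek, pkp2 and rgs10 without some library. In all 588 regions passed, 104 larger and 484 smaller in TRαKO, with a median of 0.36 over all regions and 0.18 under TMM. DESeq2 gave 41 and 656, all tags 235 and 349, and thinning 29 and 197. Of the 104 larger, 21 rose with T3 in any genotype, and of the 484 smaller 478 did. The same wild-type and TRαKO libraries entered both choices, so this overlap is largely built in. Lists had 38 smaller and 1 larger of 142, 45 and 6 adjusted over the list alone.

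Between TRβKO and wild type the T3 effect differed at fewer regions. It was smaller at the strongest thrb region (-2.01 ± 0.29, adjusted p = 1.08e-06), dot1l (-1.94 ± 0.37), thibz (-1.41 ± 0.27), wdr91 (-3.57 ± 0.65), atp13a2 (-4.41 ± 0.91) and smpd1 (-2.85 ± 0.62). The strongest thra region (-1.31 ± 0.29) lost its call without untreated TRβKO replicate 3. Calls at fcho2 (2.99 ± 0.71), lpin1, ppm1g, scrt2, cabp4, gab3, klc4, ebf4, lzts3, klhl18 and rbm12 were lost without some library. In all 167 regions passed, 25 larger and 142 smaller, with a median of -0.24 over all regions, -0.09 under TMM. TMM gave 26 and 68, all tags 34 and 58, only the libraries compared 10 and 89, and thinning 5 and 38. Leaving out untreated TRβKO replicate 2 gave 101 regions, and untreated wild-type replicate 1 or 2 gave 102 or 93. Lists had 1 larger and 10 smaller, 3 and 12 adjusted over the list alone.

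Between the knockouts the T3 effect was larger in TRβKO at abcc12 (3.76 ± 0.69), rhof (3.69 ± 0.73), fcho2 (3.41 ± 0.72), gphn (3.31 ± 0.68), the AP-1 gene fosl2 (3.09 ± 0.70), lpin1 (3.08 ± 0.67) and ensa (3.01 ± 0.54; log2 and SE). The thrb region at 46899379 (1.96 ± 0.45, adjusted p = 0.00480) passed as well. The thra region at 9098324 (1.66 ± 0.41) did so except without untreated TRαKO replicate 3. Calls at thibz, dot1l and the strongest thra region were lost without 1 of 2 or 3 libraries. The signed effect was lower in TRβKO at cacng5 (-3.89 ± 0.85), luzp2 (-3.76 ± 0.88) and opcml (-3.63 ± 0.87), the last of which fell with T3 in TRβKO. The call at cfap77 rests on 3 TRβKO reads with T3. In all 326 regions passed, 191 larger and 135 smaller, against a median of -0.55 over all regions and -0.23 under TMM. TMM gave 316 and 65, DESeq2 481 and 44, all tags 165 and 169, and thinning 54 and 21. Leaving out TRαKO replicate 2 with T3 gave 213 regions. Lists had 18 larger and 1 smaller, 23 and 5 adjusted over the list alone.

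**Figure D3:**
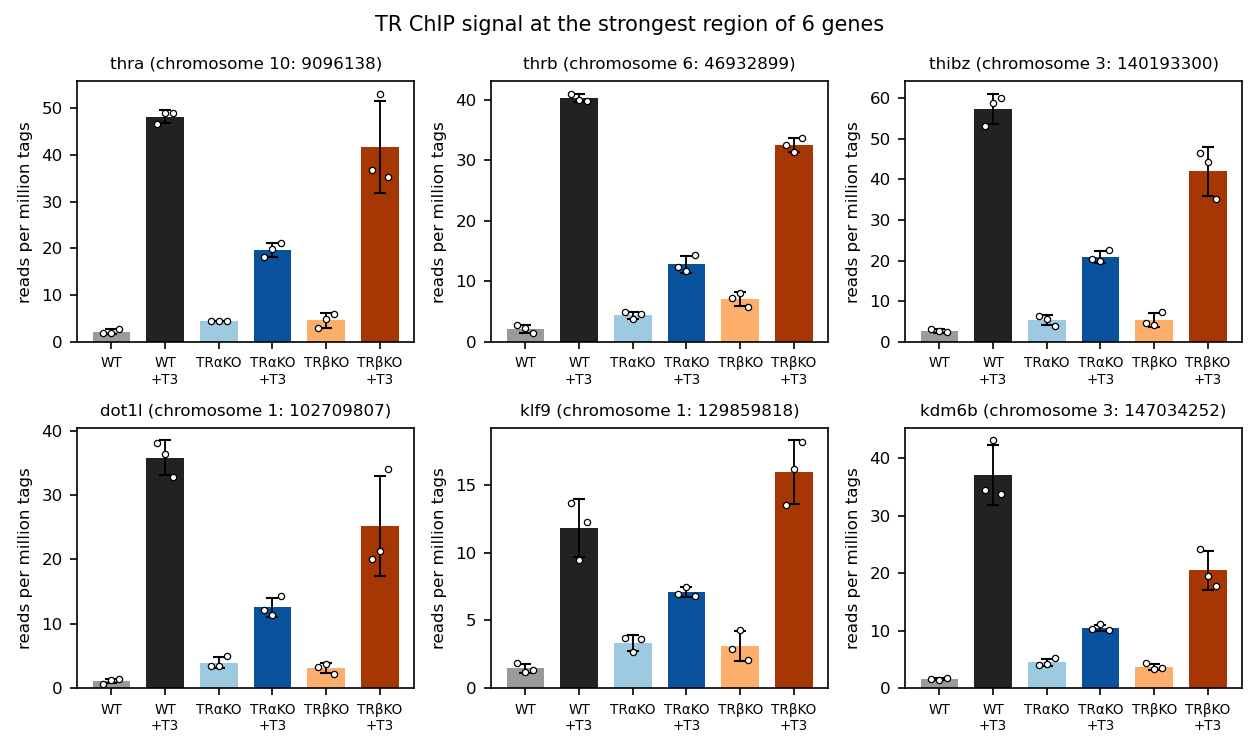
Level in CPM at the strongest counted region of 6 genes in the 6 groups, with the region's chromosome and start. Points are libraries, bars means and error bars SD of 3 libraries. At thibz the means with T3 were 57.3 in wild type, 20.9 in TRαKO and 41.9 in TRβKO, and the untreated means 2.71, 5.38 and 5.33.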

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

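The permutations of genotype labels, the tests of unequal depth and of the duplicate filter, and the test of a library batch on the T3 effect in TRαKO were chosen only after the results were seen.

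T3 effects that differed between genotypes are given here because the difference itself was tested. Between TRαKO and wild type 588 regions differed. The difference (log2) was -3.26 at dot1l, -1.90 at the klf9 region at 129859818, -2.38 and -2.91 at the thra regions at 9096138 and 9098324, and -2.44 at thibz. It was -3.03, -2.20 and -2.67 at the thrb regions at 46698245, 46899379 and 46932899. Between TRβKO and wild type 167 regions differed, with -1.94 at dot1l, -1.31 at thra (9096138), -1.41 at thibz and -1.84 and -2.01 at thrb (46698245 and 46932899). The thra call was lost without untreated TRβKO replicate 3. Between TRβKO and TRαKO 326 regions differed, with 1.31 at dot1l, 1.07 and 1.66 at thra (9096138 and 9098324), 1.03 at thibz and 1.96 at thrb (46899379). Of these, dot1l was lost without replicate 3 of untreated TRαKO, untreated TRβKO or TRβKO with T3, and thibz without untreated TRαKO replicate 1 or untreated TRβKO replicate 2. The thra region at 9096138 was lost without TRαKO replicate 1 with T3, untreated TRβKO replicate 1 or TRβKO replicate 2 with T3, and that at 9098324 without untreated TRαKO replicate 3.

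With genotype labels exchanged within treatment, 1 of 40 arrangements, the real one, gave as many regions in each of the 3 comparisons. The highest others were 212, 91 and 249 against 588, 167 and 326. With T3 labels exchanged within genotype, 1 of 40 gave as many for TRβKO against wild type (167, highest other 109), 3 of 40 for TRαKO against wild type (588, highest other 729) and 4 of 40 for TRβKO against TRαKO (326, highest other 853). Neither exchange shows whether chance can be excluded. The exchanged groups differed themselves, so mixing them widens the spread, and where labels were mixed in both strata the highest was 2. The 2 and 3 other arrangements as large kept the real T3 labels of one genotype and so set a full T3 effect against none. For the 9 comparisons of 3 libraries with 3, the splits are too few for a share under 0.05. The real counts were 1057, 810 and 1099 for T3 in wild type, TRαKO and TRβKO, 257 and 369 for TRαKO and TRβKO against wild type without T3, 783 and 395 with T3, and 58 and 970 between the knockouts. The highest other was 3 for TRβKO against wild type with T3 and 0 for the others.

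T3 added fewer reads in TRαKO than in wild type at the 887 regions that rose in TRβKO, such as thrb and dot1l (median difference -1.83 log2, -1.85 to -1.75 without 1 library, -1.99 under TMM). Thinning every library to the shallowest left -1.76, which argues against few reads in the shallow libraries as the cause. Thinning kept the regions and the expected reads per tag, so other effects of unequal depth, such as on region choice, stay open. Scaling by all tags left -1.50, which argues against the duplicate filter through library size, the only thing this scaling changes. A library batch of the untreated wild type as the whole cause is argued against by a comparison that uses no untreated library. TRαKO and wild type with T3 differed there by -1.24 (-1.25 to -1.22 without 1 library). The libraries with T3 were themselves unlike, with redundant tags of 8% to 11% in TRαKO, 16% in TRβKO and 21% to 22% in wild type. A batch of the libraries with T3 therefore cannot be told apart from genotype in that comparison. One exact fraction for all regions is argued against by the spread of the added reads around a fraction of 0.296. That spread was 1.82 times the replicate noise, where 500 simulated sets gave 0.914 to 1.10. The simulated sets held replicate noise only, so a weaker enrichment joined with other differences between library sets, such as a batch, stays open. Only 4.62% of the 887 regions gained at least as many reads per tag as in wild type. A candidate explanation is a larger part for TRα than for TRβ in the hormone-dependent signal, a hypothesis found on the same data. Different recovery of the 2 receptors by the antibody was not tested and stays open.

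Untreated TRαKO lay above untreated wild type at those 887 regions, dot1l and thibz among them (median 0.55 log2, 0.51 to 0.56 without 1 library, 0.89 under TMM, 0.43 with all tags). Untreated TRβKO did so at the 803 TRαKO risers (0.46, 0.44 to 0.52 without 1 library, 0.31 with all tags). The medians of all regions were -0.28 and -0.18. These are no neutral baseline, because regions were chosen by peaks in these libraries and untreated wild type gave the most peaks. Thinning left 0.56 in TRαKO (0.44 in TRβKO), which argues against few reads in the shallow libraries as the cause. Other effects of unequal depth stay open, because thinning kept the regions and the expected reads per tag. A library batch of the untreated wild type cannot be told apart from genotype, because 0 of its libraries lay within the 10% to 15% of redundant tags seen in the other untreated libraries, their fragment lengths were 255 to 283 against 295 to 298 elsewhere, and both knockouts were compared with the same 3 libraries. The same doubt holds for untreated TRβKO (369), the T3 effect in TRβKO against wild type (167), part of that in TRαKO (588) and the falls with T3 in wild type (101), but a shift of this size does not account for the rises in wild type, which at the 887 regions reached 11.9 CPM (median 3.38 log2) where untreated TRαKO and TRβKO held 1.80 and 1.86. A response to the loss of a receptor remains open and untested.

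On the 10 chromosomes, some regions differed from wild type the same way with and without T3, 34 in TRαKO and 40 in TRβKO, mdga2 and pde9a among them. The 2 knockouts shared 14 of them. Counted per genotype, 20 had another of the same genotype within 1 Mb, where 10000 random draws gave a median of 6 and an upper limit of 14. Draws that kept the shared regions gave 6 and 14 too. Many neighbours lie at the same locus, such as LOC101732065 on chromosome 5 (153772512, 153776957 and 153779533 in TRβKO). Strain differences in stretches of chromosome between the wild type and knockout animals would give such neighbours, but so would 1 locus counted as several regions. No input library was analysed that could separate copy number from binding, and a lasting effect of receptor loss at single regions stays open. Strain differences in stretches of chromosome do not address the mitochondrial regions left out here, of which 7 of 7 were higher in TRβKO than in wild type with and without T3.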

How the results depend on the processing

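All-tags scaling, thinning to the shallowest library and leaving out mitochondrial and scaffold regions were chosen only after the data were seen.

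Of 466 values of named regions, most kept direction and side of the threshold: 464 without the filter on low counts, 459 without mitochondrial and scaffold regions, 444 with all tags, 443 with the replicate block, 419 with only the libraries compared, 415 under TMM and 287 after thinning. DESeq2 kept 377 of the 407 it gave an adjusted p for. Without single libraries 2791 of 3324 values were kept, 512 lost their call and 17 changed sign. With the replicate block, T3 changed 1036, 775 and 1078 regions in wild type, TRαKO and TRβKO. Libraries of the same number were weakly alike (mean r 0.0171, 0.0120 and 0.0203, across regions, which are not independent replicates, against -0.00823 for different numbers). The likeness was regular, as 17 of 18 libraries were closest to those of their own number in the other groups. The number may therefore mark something these libraries shared, which the main fit leaves out. For the changes below, the cause was not tested unless named.

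TMM gave 424 regions for T3 in TRαKO, 396 for TRαKO against wild type untreated, 218 for TRβKO against wild type with T3, 55 between untreated knockouts (split reversed) and 94 for the T3 effect in TRβKO against wild type. Gene-list regions became 28, 25 and 5 (reversed) in the first 3. At thra (9147455) TRαKO against wild type untreated became 0.0144 (log2). TRβKO against wild type with T3 became 0.15 at thra (9096138) and 0.0492 and 0.0437 at thrb (46698245, 46932899), and thra (9096138) between untreated knockouts -0.12.

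DESeq2 gave 439 and 561 regions for TRαKO and TRβKO against wild type untreated, 242 for TRβKO against wild type with T3, 89 between untreated knockouts (reversed) and 525 for the T3 effect between knockouts. The same 4 region values became 0.12, 0.0175, 0.0104 and -0.13.

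Thinning removes reads and so power. It gave 356 regions for T3 in TRαKO, 35 and 46 for TRαKO and TRβKO against wild type untreated, 12 and 614 between knockouts without and with T3, and 226, 43 and 75 for the T3 effects of TRαKO and TRβKO against wild type and TRβKO against TRαKO. Signs turned at thrb (46698245) for T3 in TRαKO (0.0453), thra (9104506) and thrb (46899379) for TRαKO against wild type untreated (-1.18, -0.44), thra (9147455) for TRβKO (-0.39) and thrb (46899379) between untreated knockouts (0.78). For T3 effects they turned at thra (9147455; 3.15, 0.65 and -2.50 in the order above) and thrb (46899379; TRβKO against wild type 0.14).

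With only the libraries compared, 948 and 971 regions differed for TRαKO and TRβKO against wild type untreated (both splits reversed), 116 for TRβKO against wild type with T3 and 99 for its T3 effect. All tags gave 323 and 415 untreated, 1066 between knockouts with T3 and 334 for their T3 effect, all with the split reversed, and 92 for the T3 effect in TRβKO against wild type. At thra (9096138) the untreated knockouts differed by -0.00519, and at thrb (46899379) the T3 effect in TRβKO against wild type by 0.00758. The difference in tags per 100 between knockouts with T3 became -0.0758. Without the filter, TRβKO against wild type untreated had 392 regions (reversed).

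Peaks with -log10 q of at least 5 gave differences per library of 220 for T3 in TRβKO and 31.3 for TRβKO against wild type with T3, both reversed. Reproducible peaks became 528 in untreated wild type, 80 in untreated TRαKO, 864 in TRαKO with T3 and 71 in untreated TRβKO. Presence in all 3 libraries, a stricter demand, gave 1132 and 323 in wild type without and with T3, 104 and 579 in TRαKO and 71 and 337 in TRβKO.

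Leaving out 1 library gave 143 to 181 regions for TRαKO against wild type untreated (lowest without wild-type replicate 2), 171 to 259 for TRβKO (the same library), 35 to 43 between untreated knockouts (TRαKO replicate 3), 93 to 160 for the T3 effect in TRβKO against wild type (untreated wild-type replicate 2) and 213 to 297 between knockouts (TRαKO replicate 2 with T3). Reproducible peaks ranged over 1674 to 2744 in untreated wild type, 142 to 196 in untreated TRαKO, 797 to 1409 in TRαKO with T3 and 104 to 194 in untreated TRβKO. The peak difference between untreated knockouts ranged from -237 (without TRβKO replicate 2) to 471.

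Values near 0 changed sign. TRαKO against wild type untreated at thra (9104506) ranged over -0.17 to 0.99. TRβKO against wild type with T3 ranged over -0.0506 to 0.20, -0.0355 to 0.42 and -0.10 to 0.68 at thra (9098324, 9104506, 9147455). Untreated knockouts differed by -0.39 to 0.13 at klf9 (129859818), -0.20 to 0.26 at thra (9096138) and -0.31 to 0.13 at thibz. T3 effects differed by -0.69 to 0.11 at klf9 (129851578) and -0.61 to 0.18 at thra (9147455) for TRβKO against wild type, and -0.26 to 0.90 at thra (9104506) between knockouts.

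The response element analysis and its alternatives were not run, since no genome sequence was at hand. At the depth of wild type with T3, 8% of simulated 4-fold falls were recovered and 70% of rises.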

Other observations

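The regions below were chosen after their values were seen, and they were not tested without single libraries.

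Regions that differed from wild type with and without T3 included some in named genes. At mdga2, a neural cell adhesion gene, untreated means were 2.95 CPM in wild type, 0.0857 in TRαKO and 0.540 in TRβKO, and with T3 4.16, 0.205 and 0.676. At pde9a, a cyclic GMP phosphodiesterase gene, they were 5.65, 1.98 and 2.25 without and 9.78, 2.54 and 2.51 with T3.

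Mitochondrial reads were more frequent with T3 in every genotype. Reads in the 7 mitochondrial regions averaged 0.154 per 1000 tags without and 0.410 with T3 in wild type, 0.149 and 0.261 in TRαKO, and 0.227 and 0.807 in TRβKO. At the region at 109 the means in TRβKO and wild type were 52.4 and 40.2 CPM without T3 and 188 and 85.7 with it. What lies behind this was not tested.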
